A study of Arabidopsis thaliana with 18 samples.

How the data were processed

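Total, monosomal and polysomal RNA was sequenced from leaves of 3-week-old Arabidopsis thaliana plants of 2 genotypes, pad4-1 (the control) and upf1-3 pad4-1. Each of the 6 groups held 3 biological replicates, which gave 18 single-end, strand-specific libraries made after ribosomal RNA depletion. The deposited data were 2 gene tables, 1 with the 6 total RNA libraries and 1 with the 12 monosomal and polysomal libraries, each with 34212 loci.

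The deposited values were expected counts, that is, estimated counts per gene. Per the submitters' processing notes the tools were kallisto 0.43.0 and limma with the TAIR10 build, with no role or order given, and how transcript estimates were summed or scaled per gene was not stated. No value above 0 was exactly a whole number, and of values of at least 0.5 between 0.15 and 0.24% lay within 0.001 of one, where an even spread gives 0.2%, while each library's total lay within 0.0048 of a whole number, and totals differed between libraries, so the values were treated as estimated counts that had not been normalized to a common depth. They were rounded to whole numbers before fitting.

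Loci were matched by identifier to a supplied TAIR10.1 annotation, whose build may differ from that used by the authors, so no coordinates are given. Of the 34212 loci, 33437 (97.7%) had a match, and symbols came from that table only. Genes without a symbol there are named by locus. Reads shared between near-identical copies make the values of such genes uncertain.

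Tests were run with edgeR 4.0.16 in R 4.3.3 as quasi-likelihood fits on genes that passed filterByExpr with a count minimum of 10, with TMM scaling and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05, two-sided. Total RNA was fitted alone (6 libraries, 4 residual degrees of freedom), monosomal and polysomal RNA together (12 libraries, 8), and the polysome-to-total comparison over all 18 libraries (12). The contrasts were mutant against control in each kind of RNA, polysome against monosome within each genotype, the difference of that ratio between genotypes, and the difference of the polysome-to-total ratio between genotypes, the last 2 as interaction terms. Values per library are CPM, that is, counts scaled to a common TMM-scaled library size, with the mean and SD of 3 libraries. A standard error (SE) of a log2 fold change is its size over the square root of F. A library with no count allows a level of up to 3 counts, and this floor and the 95% Wilson intervals of shares cover counting error only, since reads without molecular identifiers are not independent molecules.

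The contrasts, the tests, the gene lists and the rule for named genes were chosen before the data were examined. That rule took UPF1 and PAD4 in each library. It also took the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, a mean log2 CPM of at least 3 and no overlap between the libraries of both groups (the last condition did not apply to interactions). Last, it took up to 4 members with the smallest p in each list described. Some genes that this rule takes are not reported here. The 22 lists held NMD and exon junction complex factors, splicing regulators with known poison-exon or retained-intron isoforms, genes with a conserved upstream open reading frame, mRNA decay factors outside NMD, NLR immune receptors, salicylic acid and basal defence genes, jasmonate genes, nuclear photosynthesis genes, cytosolic ribosomal proteins, translation initiation and elongation factors, flowering time regulators, circadian clock genes, endoplasmic reticulum stress genes, heat shock genes, rapid touch, wound and cold response genes, senescence genes, long non-coding and trans-acting siRNA precursor RNAs, and markers of vascular tissue, of guard and myrosin cells, of epidermis and trichomes, of root hairs, and of flowers and seeds. Of their entries, 382 were used and 10 were dropped because the locus was missing from the tables or its symbol belonged to another locus.

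Features linked to NMD were computed from the annotation for protein-coding genes with annotated UTRs: a transcript with an exon junction more than 50 nt after its stop codon, a 3 prime UTR over 350 nt, and an upstream open reading frame of at least 16 codons. Non-coding RNA genes and pseudogenes were compared with all tested genes, and transposable elements were not used here. Lists and classes with at least 3 tested members were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted within each contrast and family. Beside it stand camera with an estimated correlation, which treats a list whose members vary together more strictly, and fry, which asks whether the members move one way on balance.

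Depth ran from 16325537 to 81528839 estimated counts per library. On counts simulated with the spread of these libraries, the test recovered 46.9% of 4-fold and 83.7% of 8-fold changes in total RNA, 40.0% and 68.8% in monosomal RNA, and 59.2% and 65.3% in polysomal RNA. Changes of 2-fold were recovered in 2.0, 4.0 and 0% of cases. For the polysome-to-monosome ratio the shares were 40.0 and 51.0% in the control and 42.9 and 58.3% in the mutant. For its difference between genotypes they were 6.0 and 28.6%, and for the polysome-to-total difference 6.2 and 31.9%. In the total RNA simulation 10 of 75 calls (13.3%) were genes that had not been changed. Each simulation changed 50 genes at each fold size, far fewer than were called between genotypes in the real libraries. The Benjamini-Hochberg threshold is stricter with fewer changed genes, so recovery in the genotype comparisons may have been higher.

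Libraries of a group were checked for repeat deposits, and the lowest chi-square per degree of freedom between replicates was 35.3, so no pair was a copy. Whether replicate numbers mark shared plants was checked by correlating, across genes, the deviations of libraries from their group means. Monosomal and polysomal libraries of the same number correlated at 0.474, 0.123 and 0.218 in the control and at 0.327, 0.263 and 0.174 in the mutant. They were each other's best partners except for control number 2, where both libraries correlated best with number 3. The numbers thus pair most of these fractions, whether through shared plants or a shared batch. Values with genotype by number as a block are given for the gene counts within each genotype and for lists whose call changed, not for named genes. Between genotypes the correlations were 0.181, -0.011 and 0.11 in total RNA, 0.152, 0.116 and -0.009 in monosomal and 0.105, 0.18 and -0.181 in polysomal RNA. Numbers 1 and 3 in total RNA and 1 and 2 in monosomal RNA were mutual best partners, and no number was in polysomal RNA. Pairing between genotypes is therefore unclear, and it was not used in the main fits.

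The alternatives were DESeq2 size factors in edgeR, no TMM, no low-count filter, a count minimum of 50, organelle genes left out, a threshold of 0.01, a 2-fold minimum, DESeq2 1.42.0, limma-voom, replicate number as a block, genotype by number as a block, the libraries of a contrast alone, and each library left out in turn. After the data had been seen, 4 further kinds were added: the omission of the most chloroplast-rich control libraries (monosomal and polysomal replicate 1), the omission of mutant total RNA replicates 2 and 3, which stand apart in defence and clock genes (1 library is then left in that group, and the spread comes from the others), blocked list tests of the polysome-to-monosome ratio, and shared calls with each library left out in turn. Other splits of the libraries were run for each gene-wide test. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.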

Results

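The study measured leaf RNA of the pad4-1 control and of the upf1-3 pad4-1 double mutant (hereafter the mutant) in 3 forms: total RNA, RNA bound by single ribosomes (monosomal) and RNA bound by several ribosomes (polysomal). UPF1 is the RNA helicase at the centre of nonsense-mediated mRNA decay (NMD), a pathway that degrades transcripts with premature stop codons and other features that mark abnormal translation termination. PAD4 is a regulator of salicylic acid defence, and its loss is known to ease the autoimmune growth defects of Arabidopsis NMD mutants. Each of the 6 groups had n = 3 libraries. Replicates 1, 2 and 3 of control total RNA held 66028073, 50919005 and 67094214 estimated counts, and those of mutant total RNA 53297699, 81528839 and 65793646. Monosomal libraries held 46774327, 31618627 and 16325537 in the control and 54702421, 33001713 and 30475193 in the mutant. Polysomal libraries held 41932955, 29775965 and 23631313 in the control and 51877919, 33498339 and 27259506 in the mutant.

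Chloroplast genes took 41.0% ± 6.16 (SD, n = 3) of the counts in control total RNA and 51.5% ± 6.76 in mutant total RNA. Their share was 41.6% ± 15.8 and 27.0% ± 8.31 in monosomal RNA of control and mutant, and 53.0% ± 18.6 and 41.0% ± 10.7 in polysomal RNA. The control monosomal and polysomal libraries of replicate 1 stood apart at 59.86% (95% Wilson interval 59.85 to 59.88) and 74.13% (74.12 to 74.15). Nuclear ribosomal RNA took 10.39% (10.38 to 10.39) of the counts in mutant total RNA replicate 2, against 0.253% ± 0.093 in control total RNA.

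UPF1 and PAD4, the mutated genes, were followed in each library. In total RNA, UPF1 stood at 69.3 ± 7.23 CPM (SD, n = 3) in the control and 33.4 ± 7.58 CPM in the mutant (log2 fold change -1.05, SE 0.24, adjusted p = 0.0159). The call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0504, 0.0784 and 0.0559). In monosomal RNA, UPF1 stood at 45.9 ± 2.76 CPM in the control and 40.1 ± 2.96 CPM in the mutant (-0.19, SE 0.30, adjusted p = 0.724, with a positive sign without TMM). In polysomal RNA it stood at 48.6 ± 1.86 and 41.6 ± 21.1 CPM (-0.23, SE 0.30, adjusted p = 0.705, with a positive sign without TMM), where mutant replicates 1, 2 and 3 had 26.4, 32.7 and 65.6 CPM. PAD4 stood at 1.47 ± 0.266 CPM in control total RNA and at 3.57, 40.5 and 4.42 CPM in mutant replicates 1, 2 and 3 (3.45, SE 0.94, adjusted p = 0.0298). Without control replicate 1, 2 or 3 its adjusted p was 0.102, 0.105 and 0.102, and without mutant replicate 2 its log2 fold change was 1.46. PAD4 was not called in monosomal (2.03, SE 1.03, adjusted p = 0.211) or polysomal RNA (2.82, SE 1.07, adjusted p = 0.0949, and 0.0352 without control monosomal replicate 3). The labels do not say where the upf1-3 insertion lies, so these levels do not test the genotype.

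**Figure D1:**
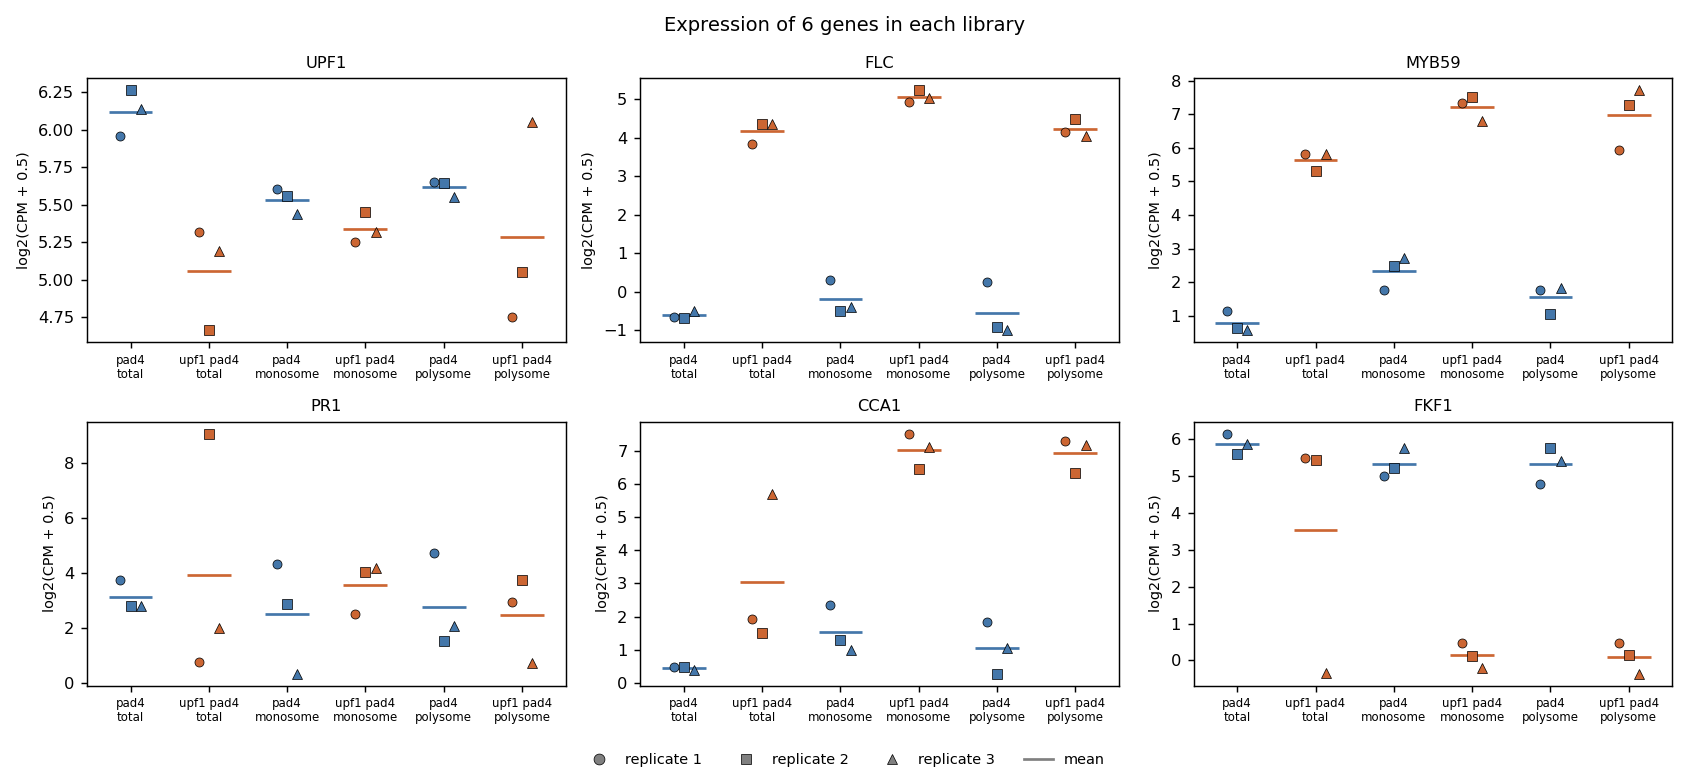
Log2 of CPM plus 0.5 (y axis) in each library of the 6 groups (x axis) for UPF1, FLC, MYB59, PR1, CCA1 and FKF1, with a marker per replicate and a line at the group mean. FLC and MYB59 are higher in all mutant libraries of each RNA, while PR1 in total RNA stands out in mutant replicate 2 and CCA1 and FKF1 in mutant replicate 3.

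The comparison of the genotypes in total RNA asks which transcripts accumulate or decline when UPF1 is impaired. FLC, the MADS-box repressor of flowering, rose 112-fold, from 0.159 ± 0.041 to 17.96 ± 3.63 CPM (SD, n = 3; log2 fold change 6.80, SE 0.35, adjusted p = 0.000594). GolS2, a galactinol synthase of the raffinose pathway, rose 125-fold (6.96, SE 0.72, adjusted p = 0.00157), and the transcription factor gene MYB59 rose 40-fold, from 1.25 ± 0.413 to 50.4 ± 9.48 CPM (5.32, SE 0.33, adjusted p = 0.000594). The other highest changes were MRD1 (6.77, SE 0.56), the receptor-like kinase gene CRK24 (6.34, SE 0.89), OASA2 of cysteine synthesis (5.51, SE 0.72), the clock gene PRR9 (5.44, SE 0.78) and WAK3, a wall-associated kinase gene (5.52, SE 1.63). WAK3 rested on mutant replicate 2: its log2 fold change was 1.35 without that library (adjusted p = 0.104), and its adjusted p was 0.137, 0.117 and 0.129 without control replicate 1, 2 or 3. Genes of cell division stood among the lowest: HIS4 (a histone H4, -2.79, SE 0.45), the cytokinesis kinesin gene HIK (-2.79, SE 0.43), the cytokinesis syntaxin gene SYP111 (-2.78, SE 0.49), 3xHMG-box2 (-2.74, SE 0.43) and the topoisomerase gene TOPII (-2.48, SE 0.32). CSD2, a chloroplast copper/zinc superoxide dismutase, fell from 242 ± 60.1 to 32.7 ± 7.72 CPM (-2.89, SE 0.30, adjusted p = 0.00161), and the germin-like gene GER3 fell by 2.59 (SE 0.36). FTM1 fell by 3.83 (SE 0.84), with an adjusted p of 0.0551 and 0.0501 without control replicate 1 or 2.

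Lists of genes with isoforms known as NMD targets were tested on gene-level sums, which do not show single isoforms. Of 20 tested splicing regulators with poison-exon or retained-intron isoforms, 13 rose, 1 fell and 6 were not called (14 and 1 adjusted over the list alone, median log2 fold change 1.43; camera adjusted p = 1.89e-06, adjusted p = 0.208 with an estimated correlation). SCL33 rose by 2.69 (SE 0.19), TFIIIA by 2.34 (SE 0.20), the polypyrimidine tract-binding gene PTB2 by 1.96 (SE 0.19) and RS31A by 2.25 (SE 0.26). Of 27 genes with a conserved upstream open reading frame, 12 rose and none fell (15 adjusted over the list alone, median 0.99; adjusted p = 1.91e-05, adjusted p = 0.208 with an estimated correlation). SAC51, which acts in thermospermine-dependent xylem development, rose by 2.91 (SE 0.24), the kinase gene CIPK6 by 3.08 (SE 0.33) and EMB1444 by 2.07 (SE 0.20). Among 11 NMD and exon junction complex factors, 3 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.994). Of 25 decay factors outside NMD, 2 rose and 2 fell (2 and 1 adjusted over the list alone, adjusted p = 0.681). The deadenylase gene CAF1A rose by 2.23 (SE 0.33).

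The features linked to NMD pointed the same way. Genes with an exon junction more than 50 nt after a stop codon rose in 22.8% of 1914 cases, against 13.1% of the other genes with annotated UTRs (437 rose, 122 fell, 448 and 128 adjusted over the class alone; adjusted p = 0.000169, and 0.00435 with an estimated correlation). Of 7356 genes with an upstream open reading frame of at least 16 codons, 1295 rose and 681 fell (1269 and 662 adjusted over the class alone, adjusted p = 0.0129). Of 6639 with a 3 prime UTR over 350 nt, 1066 rose and 652 fell (0.0436), a call lost without control replicate 1 or 2 or mutant replicate 1 (0.0553, 0.0504 and 0.0795). Of all 20302 genes 3107 rose and 2531 fell, so both classes rose little more often but fell less. Of 326 non-coding RNA genes 119 rose and 9 fell (1.13e-09, and 0.0626 with an estimated correlation), and of 364 pseudogenes 143 and 4 (2.73e-10, and 0.0363 likewise).

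Defence genes were higher in the mutant, and unevenly so. Of 34 tested NLR immune receptors, which detect pathogen effectors, 12 rose and none fell (12 adjusted over the list alone, median 0.83; adjusted p = 0.000164, adjusted p = 0.526 with an estimated correlation). WRR4 rose by 2.00 (SE 0.20), RPS6 by 1.48 (SE 0.18) and TAO1 by 2.08 (SE 0.27). The list's median against the control mean was 0.49, 1.03 and 0.36 in mutant replicates 1, 2 and 3. Of 28 salicylic acid and basal defence genes, 10 rose and none fell (13 adjusted over the list alone, median 3.22; adjusted p = 0.0122, adjusted p = 0.768 with an estimated correlation), but their median was 0.10, 4.33 and 0.35 in the 3 mutant replicates, and without replicate 2 the list was not called (adjusted p = 0.255). PR1, the classic salicylic acid marker, stood at 8.72 ± 3.79 CPM in the control and at 1.19, 536.7 and 3.55 CPM in mutant replicates 1, 2 and 3. Replicate 2 also held the high share of nuclear ribosomal RNA. Senescence genes (4 of 8 rose, 8 adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.685 with an estimated correlation) and rapid touch, wound and cold response genes (3 of 11 rose, 6 adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.526 with an estimated correlation) were higher too. Their medians in mutant replicates 1, 2 and 3 were 0.51, 2.49 and 1.01 for senescence and 0.71, 2.71 and 0.5 for touch genes, so replicate 2 was the highest in both. Without that library the adjusted p was 0.0418 and 0.0123 (0.438 and 0.426 with an estimated correlation). WRKY40 rose by 3.95 (SE 0.51) and ZAT10 by 4.17 (SE 0.60). Of 9 heat shock genes 3 rose (3 adjusted over the list alone, adjusted p = 0.0391, adjusted p = 0.646 with an estimated correlation), HSP70 (AT3G12580) by 4.28 (SE 0.46). That call was lost without control replicate 2 or 3 or mutant replicate 1 or 2 (adjusted p = 0.0627, 0.151, 0.078 and 0.0523).

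Genes of protein synthesis and photosynthesis declined. Of 37 cytosolic ribosomal protein genes 32 fell and none rose (36 adjusted over the list alone, median -1.36; adjusted p = 4.16e-15, adjusted p = 0.208 with an estimated correlation), with RPL3A lower by a log2 fold change of -1.97 (SE 0.23) and RPL23AA by -2.17 (SE 0.26). Of 20 translation factors 13 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.99; adjusted p = 9.51e-06, adjusted p = 0.208 with an estimated correlation), among them the poly(A)-binding gene PAB4 (-1.76, SE 0.21) and the cap-binding gene EIFISO4E (-1.86, SE 0.27). Of 38 nuclear photosynthesis genes 22 fell and none rose (26 adjusted over the list alone, median -1.16; adjusted p = 9.72e-10, adjusted p = 0.526 with an estimated correlation), such as PSBP1 of photosystem II (-1.71, SE 0.27) and PSAF of photosystem I (-1.63, SE 0.27). Their median was -1.29, -1.68 and -0.81 in mutant replicates 1, 2 and 3, in libraries where the chloroplast transcript ATCG00020 took 36.31% (95% Wilson interval 36.29 to 36.32), 30.49% (30.48 to 30.5) and 35.83% (35.82 to 35.84) of all counts.

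Other lists were not called as groups in total RNA. Among 18 flowering time regulators 5 rose and 3 fell (5 and 4 adjusted over the list alone), including the FLC relatives FLM (1.41, SE 0.20) and MAF3 (2.23, SE 0.33). Their median was -0.55 and their mean 0.33 (adjusted p = 0.681). Of 14 circadian clock genes 3 rose and none fell (3 adjusted over the list alone, adjusted p = 0.681), a list called upward without mutant replicate 3 (adjusted p = 0.0155, adjusted p = 0.19 with an estimated correlation). In that replicate the morning genes CCA1 and LHY stood at 51.5 and 131.9 CPM, against 3.27 and 0.948 CPM in replicate 1 and 2.33 and 1.81 CPM in replicate 2. Jasmonate genes (6 of 22 rose, 7 adjusted over the list alone, adjusted p = 0.19) were called upward without control replicate 1 (0.0435) or mutant replicate 3 (0.0343). Those calls had adjusted p = 0.766 and 0.654 with an estimated correlation. Their median was 0.27, 1.52 and 0.07 in mutant replicates 1, 2 and 3, and without replicate 2 it was 0.327 (adjusted p = 0.697). Endoplasmic reticulum stress genes had 2 of 11 rise (2 adjusted over the list alone, adjusted p = 0.26), and long non-coding and siRNA precursor RNAs 1 of 6 (1 adjusted over the list alone, median -0.21, mean 0.85; adjusted p = 0.681). The marker lists were not called: vascular (1 of 4 fell; 1 adjusted over the list alone, adjusted p = 0.299), guard and myrosin cells (0 of 6; 0.228), epidermis and trichomes (0 of 3; 0.26, but 0.0426 without mutant replicate 3, adjusted p = 0.554 with an estimated correlation) and flowers and seeds (0 of 5; median -1.64; 0.105, but 0.0467 without control replicate 3, adjusted p = 0.788 with an estimated correlation). None of the 4 root hair markers passed the count filter.

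In all, edgeR called 5638 of 20302 tested genes in total RNA, 3107 higher and 2531 lower in the mutant, and 4676 of them changed at least 2-fold. The libraries of the genotypes did not overlap for 47.9% of tested genes, where chance gives 10%. Without TMM the median log2 fold change of all genes moved from 0.03 to -0.135. Without control replicate 1, 2 or 3 the test called 2291, 2047 and 2921 genes. Of 93 tested mitochondrial genes 21 rose and 1 fell, and of 79 chloroplast genes 1 rose and 5 fell.

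**Figure D2:**
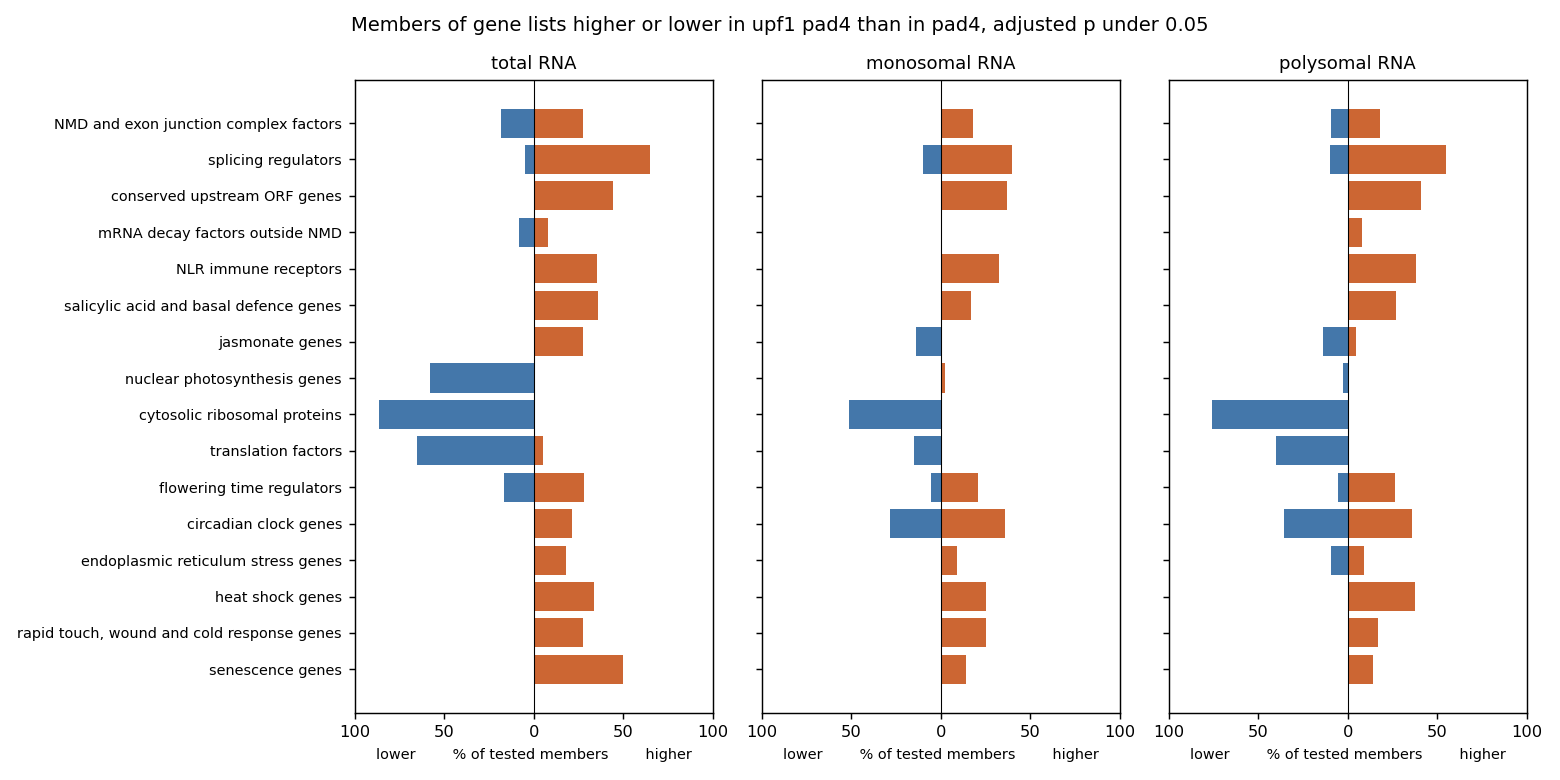
Percent of tested members of each list that were higher (orange, to the right) or lower (blue, to the left) in the mutant, in total, monosomal and polysomal RNA, for lists with at least 8 tested members. Ribosomal protein genes lie on the lower side in all 3 kinds of RNA, and splicing regulators, genes with a conserved upstream open reading frame and NLR receptors on the higher side.

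In monosomal RNA, where the comparison asks which changes reach ribosome-bound RNA, clock genes stood among the highest and lowest changes. CCA1 and LHY, the morning transcription factors of the clock, rose from 2.69 ± 1.70 to 136 ± 47.4 CPM (SD, n = 3; 5.64, SE 0.57, adjusted p = 4.16e-05) and by 5.62 (SE 0.73), RVE8 rose by 6.54 (SE 0.61) and PRR9 by 5.55 (SE 0.70). FKF1, the evening blue-light receptor, fell from 40.7 ± 11.5 to 0.619 ± 0.258 CPM (-6.00, SE 0.48, adjusted p = 5.94e-06), and the clock-controlled genes GRP7 and COR27 fell by 5.44 (SE 0.64) and 5.30 (SE 0.67). FLC rose by 6.30 (SE 0.77), MRD1 by 6.73 (SE 0.71), COL2 by 5.42 (SE 0.52) and BBX16 by 5.31 (SE 0.90). Among 14 clock genes 5 rose and 4 fell (5 and 6 adjusted over the list alone, median -0.12, mean 0.74, adjusted p = 0.982).

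LTP12 and ATA27, both known from the anther tapetum, stood at 0.4, 51.3 and 39.6 CPM and at 2.71, 45.2 and 30.6 CPM in control monosomal replicates 1, 2 and 3, and at means of 0.0558 ± 0.0637 and 0.0764 ± 0.0498 CPM in the mutant (adjusted p = 0.00388 and 0.000557). The limma-voom test did not call LTP12, ATA27, PI or CYP96A15. Of 5 flower and seed markers 2 fell (3 adjusted over the list alone, median -3.34; adjusted p = 0.0284, adjusted p = 0.382 with an estimated correlation). The floral identity gene PI stood at 1.54, 19.6 and 19.3 CPM in control replicates 1, 2 and 3 and at 0.447 ± 0.56 CPM in the mutant (-4.85, SE 1.18, adjusted p = 0.0142, and 0.0516 without mutant replicate 2). CYP96A15 of wax synthesis fell by 4.62 (SE 1.2). Its adjusted p was 0.0632, 0.0653 and 0.0597 without control replicate 2 or mutant replicate 1 or 3. The neighbouring loci AT3G28290 and AT3G28300 are near-identical copies, so their shared change of -4.15 (SE 0.63) is uncertain.

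In monosomal RNA, of 20 splicing regulators 8 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.86; adjusted p = 0.00339, adjusted p = 0.249 with an estimated correlation), SCL33 by 2.55 (SE 0.37) and PTB2 by 1.97 (SE 0.29). Of 27 genes with a conserved upstream open reading frame 10 rose (15 adjusted over the list alone, median 1.27; adjusted p = 7.45e-06, adjusted p = 0.0761 with an estimated correlation), AT5G09460, a relative of SAC51, by 2.68 (SE 0.28). Of 34 NLR receptors 11 rose (16 adjusted over the list alone, median 0.71; adjusted p = 5.9e-06, adjusted p = 0.249 with an estimated correlation). WRR4 rose by 2.28 (SE 0.37) and TAO1 by 3.04 (SE 0.55). Of 30 salicylic acid genes 5 rose (6 adjusted over the list alone, median 1.27; adjusted p = 0.000566, adjusted p = 0.249 with an estimated correlation), WRKY46 by 3.22 (SE 0.41), and that median was 1.12, 0.79 and 0.73 in mutant replicates 1, 2 and 3. Of 11 NMD factors 2 rose (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.437), and none of 25 decay factors was called (adjusted p = 0.437). Genes with a late exon junction rose in 12% of 1937 cases against 7.4% of the others (adjusted p = 0.00937, adjusted p = 0.139 with an estimated correlation). The classes with a long 3 prime UTR (adjusted p = 0.114) or an upstream open reading frame (0.0721) were not called, though the latter was without control monosomal replicate 1 (0.0397, adjusted p = 0.119 with an estimated correlation). Non-coding RNA genes (46 rose, 2 fell; 0.00457, and 0.62 with an estimated correlation) and pseudogenes (53 rose, 2 fell; 0.0374, and 0.62 with an estimated correlation) were higher.

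Ribosomal protein genes fell in 19 of 37 cases (31 adjusted over the list alone, median -1.07; adjusted p = 7.61e-14, adjusted p = 0.227 with an estimated correlation), RPL24A by 1.58 (SE 0.31). Translation factors fell in 3 of 20 cases (3 adjusted over the list alone, adjusted p = 7.58e-05, adjusted p = 0.227 with an estimated correlation). Jasmonate genes fell in 3 of 22 cases (1 rose and 4 fell adjusted over the list alone, adjusted p = 0.0246, adjusted p = 0.249 with an estimated correlation), CORI3 by 1.63 (SE 0.35), a call lost without control replicate 2 (0.0851) or mutant replicate 1 (0.138). Guard and myrosin cell markers fell in 1 of 6 cases (1 adjusted over the list alone, 0.0246, adjusted p = 0.227 with an estimated correlation), a call lost without mutant replicate 1 (0.0787). Photosynthesis genes differed between mutant replicates 1, 2 and 3, with medians of -1.18, 0.10 and 0.61; 1 of 38 rose and none did adjusted over the list alone, and the median was 0.06 while the test pointed down (adjusted p = 0.437). That list was called upward without mutant replicate 1 (0.0182) and downward without mutant replicate 3 (0.000365). The adjusted p was 0.652 and 0.564 with an estimated correlation. Touch, wound and cold genes (3 of 12 rose, 4 adjusted over the list alone, 0.0177, adjusted p = 0.227 with an estimated correlation) were higher, TCH3 by 2.08 (SE 0.29). Senescence genes (1 of 7 rose, 2 adjusted over the list alone, 0.0422, adjusted p = 0.227 with an estimated correlation) lost their call without mutant replicate 1 (0.0793) or 2 (0.0546). Heat shock genes were not called (2 of 8 rose, 2 adjusted over the list alone, 0.0569), but were called without control monosomal replicate 2 (0.0374) or 3 (0.0446), control polysomal replicate 2 (0.0492), mutant monosomal replicate 2 (0.044) or 3 (0.0116), or mutant polysomal replicate 1 (0.0362) or 2 (0.0461). With an estimated correlation the adjusted p was 0.245 to 0.412. Vascular markers were not called (0 of 4, 2 lower adjusted over the list alone, 0.0597), but were called downward without control monosomal replicate 2 (0.0453) or 3 (0.0414), mutant monosomal replicate 3 (0.0296), or mutant polysomal replicate 1 (0.0358) or 2 (0.0365). These had adjusted p = 0.216 to 0.294 with an estimated correlation. Flowering time regulators (4 rose and 1 fell of 19, 5 and 3 adjusted over the list alone, 0.78) and genes of stress in the endoplasmic reticulum (1 of 11 rose, 1 higher and 2 lower adjusted over the list alone, 0.197) gave no call. The same held for siRNA precursors (0 of 7, 0.937) and epidermis markers (0 of 3, 1 lower adjusted over the list alone, 0.779).

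In total 2647 of 20895 genes were called in monosomal RNA, 1686 higher and 961 lower, with no overlap between genotypes for 31.1% of tested genes (chance gives 10%). Without TMM the median log2 fold change of all genes moved from 0.019 to 0.62 and the share of calls that were higher went from 63.7% to 95.5%, so changes here are relative to the TMM scale. Without control monosomal replicate 2 or 3 the counts were 1378 and 1541.

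Polysomal RNA gave a similar picture under the same limit. LHY rose by 7.16 (SE 0.78), PRR9 by 6.98 (SE 0.75), RVE8 by 6.51 (SE 0.62) and CCA1 by 6.15 (SE 0.59, adjusted p = 1.7e-05), while FKF1 fell by 6.02 (SE 0.48), COR27 by 5.90 (SE 0.69) and GRP7 by 5.06 (SE 0.63). FLC rose to 18.4 ± 3.16 CPM (SD, n = 3; 6.35, SE 0.81, adjusted p = 0.000125), GolS2 by 6.25 (SE 0.74), MRD1 by 6.13 (SE 0.66) and MYB59 by 5.81 (SE 0.50). The jasmonate-responsive gene VSP1 fell by 5.77 (SE 1.36), the amylase gene BAM5 by 4.88 (SE 1.12), BT2 by 4.17 (SE 0.37) and the tapetum gene ATA27 stood lower (-6.27, SE 1.21). LTP12 stood at 0.15, 3.88 and 7.43 CPM in control replicates 1, 2 and 3 and had no counts in the mutant libraries, which allows 0.0446, 0.0734 and 0.141 CPM in mutant replicates 1, 2 and 3.

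Splicing regulators rose in 11 and fell in 2 of 20 cases (11 and 2 adjusted over the list alone, median 0.98; adjusted p = 0.00168, adjusted p = 0.321 with an estimated correlation), with TFIIIA up by 3.19 (SE 0.39) and PTB2 by 2.40 (SE 0.29). Of 27 genes with a conserved upstream open reading frame 11 rose (13 adjusted over the list alone, median 1.32; adjusted p = 1.78e-07), the 1 list call kept with an estimated correlation (adjusted p = 0.03). CIPK6 rose by 4.31 (SE 0.44), AT5G09460 by 2.99 (SE 0.28) and PMEAMT, a phosphoethanolamine methyltransferase of phosphocholine synthesis, by 4.48 (SE 0.61). Of 34 NLR receptors 13 rose (18 adjusted over the list alone, median 0.91; adjusted p = 4.67e-09, adjusted p = 0.232 with an estimated correlation). WRR4 rose by 2.94 (SE 0.37) and CHS3 by 2.13 (SE 0.36). Of 30 salicylic acid genes 8 rose (8 adjusted over the list alone, median 1.55; adjusted p = 2.31e-05, adjusted p = 0.232 with an estimated correlation), DMR6 by 3.68 (SE 0.59). Heat shock genes rose in 3 of 8 cases (4 adjusted over the list alone, median 2.08; adjusted p = 0.0169, adjusted p = 0.321 with an estimated correlation), HSP70 by 5.16 (SE 0.69). Of 37 ribosomal protein genes 28 fell (34 adjusted over the list alone, median -1.35; adjusted p = 4.77e-23, adjusted p = 0.166 with an estimated correlation), RPL10A by 1.65 (SE 0.32), and of 20 translation factors 8 fell (10 adjusted over the list alone, adjusted p = 6.21e-08, adjusted p = 0.138 with an estimated correlation).

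Clock genes again went both ways in polysomal RNA (5 rose and 5 fell of 14; 5 and 6 adjusted over the list alone, median -0.37, mean 0.45; adjusted p = 0.768). Flowering time regulators rose in 5 and fell in 1 of 19 cases (5 and 4 adjusted over the list alone, 0.768), NMD factors in 2 and 1 of 11 (4 and 2 adjusted over the list alone, 0.563), and decay factors rose in 2 of 25 (2 adjusted over the list alone, median -0.16, mean 0.11; 0.813). Jasmonate genes (1 rose, 3 fell; 2 and 4 adjusted over the list alone, 0.096, but 0.0176 without control replicate 1, adjusted p = 0.136 with an estimated correlation), photosynthesis genes (1 of 38 fell, none adjusted over the list alone, 0.0502) and touch genes (2 of 12 rose, 2 adjusted over the list alone, 0.096) were not called. The photosynthesis list was called downward without control monosomal replicate 1 (0.0436), 2 (0.0332) or 3 (0.0408), control polysomal replicate 1 (0.00107), mutant monosomal replicate 1 (0.0142), 2 (0.0472) or 3 (0.0317), or mutant polysomal replicate 3 (0.000287). No such omission kept the call with an estimated correlation (adjusted p = 0.611 to 0.747). Touch genes were called without control polysomal replicate 2 (0.0472) or 3 (0.0489) or mutant polysomal replicate 2 (0.039). Their adjusted p was 0.238 to 0.311 with an estimated correlation. Senescence genes (1 of 7 rose, 1 adjusted over the list alone, 0.146) and siRNA precursors (1 of 7 rose, 1 adjusted over the list alone, 0.486) were not called. Endoplasmic reticulum stress genes (1 rose and 1 fell of 11, 1 and 1 adjusted over the list alone, 0.194) were called downward without mutant polysomal replicate 2 (0.0254, adjusted p = 0.343 with an estimated correlation). No call came from vascular (0 of 4, 0.278), guard cell (0 of 6, 0.25), epidermis (0 of 3, 0.486) or flower markers (0 of 5, 0.278). In a test chosen after the results were seen, flower markers were called downward without control monosomal and polysomal replicate 1 (median -1.97, 0.0146, adjusted p = 0.326 with an estimated correlation). Genes with a late exon junction rose in 13% of 1937 cases against 7.6% of the others (adjusted p = 0.013, adjusted p = 0.201 with an estimated correlation), a call lost without control polysomal replicate 3 (0.0725). Those with an upstream open reading frame rose in 10.4% against 6.7% (0.0432, adjusted p = 0.201 with an estimated correlation), a call lost without control polysomal replicate 2 (0.0612) or 3 (0.105) or mutant polysomal replicate 3 (0.105). A long 3 prime UTR gave no call (0.183). Non-coding RNA genes (51 rose, none fell; 1.63e-05, and 0.315 with an estimated correlation) and pseudogenes (61 rose, none fell; 1.73e-05, and 0.315 with an estimated correlation) were higher.

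Of 20895 genes 2796 were called in polysomal RNA, 1742 higher and 1054 lower, with no overlap between genotypes for 38.0% of tested genes (chance gives 10%). Without TMM the median moved from 0.033 to 0.471 and the higher share of calls from 62.3% to 95.7%. Without control polysomal replicate 2 or 3 or mutant polysomal replicate 3 the counts were 1572, 1432 and 1418.

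**Figure D3:**
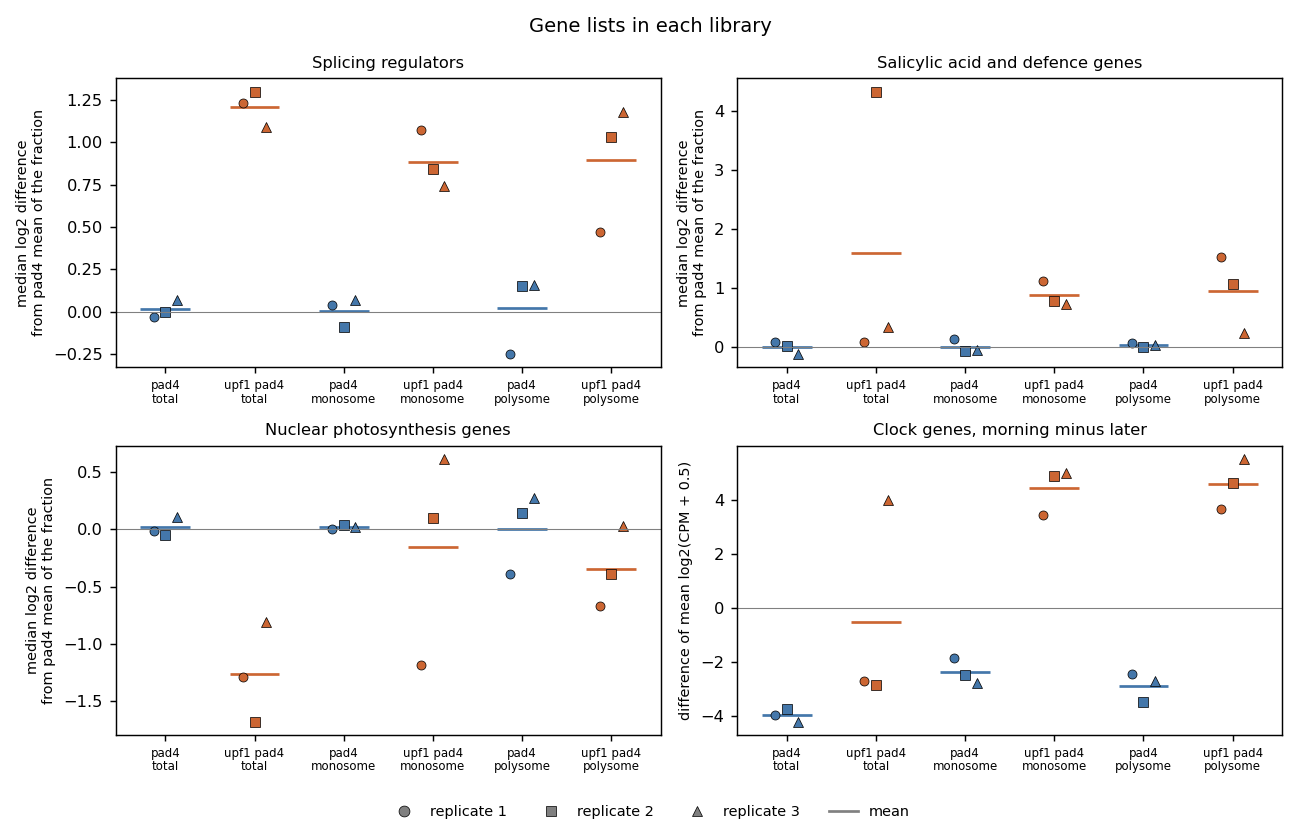
Median log2 difference from the control mean of the same kind of RNA (y axis) for splicing regulators, salicylic acid genes and photosynthesis genes in each library (x axis), and the clock index, the mean log2 level of morning genes minus that of later genes. Splicing regulators are higher in every mutant library, salicylic acid genes stand out in mutant total RNA replicate 2, and the clock index is positive in mutant total RNA replicate 3 and in all mutant monosomal and polysomal libraries.

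Changes were shared between the 3 kinds of RNA. Of 19930 genes tested in all 3, 843 were higher and 325 lower in the mutant in each, FLC, SCL33, TFIIIA, CIPK6 and WRR4 among the former. Total and monosomal RNA shared 1058 higher and 473 lower genes, against 254.1 and 117.1 for independent lists, with 3 genes called in opposite directions (Pearson r across genes 0.613). Total and polysomal RNA shared 1188 and 634, against 264.1 and 131.6, with 2 opposite (r 0.701), and monosomal and polysomal RNA 1171 and 568, against 140.6 and 48.5, with none opposite (r 0.659). Left out singly, control total RNA replicate 1 or 2, control monosomal replicate 2 or 3 or mutant monosomal replicate 1 took the 1531 genes shared by total and monosomal RNA to 999, 922, 889, 959 and 1016. Without control total RNA replicate 1 or 2, control polysomal replicate 2 or 3 or mutant polysomal replicate 3, the 1822 shared by total and polysomal RNA became 1185, 1068, 1095, 964 and 976. The 1739 shared by monosomal and polysomal RNA became 1058 without control monosomal replicate 2, and 1148 and 1073 without control polysomal replicate 2 or 3. Genes are not independent replicates, and monosomal and polysomal libraries of a number have correlated deviations.

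The comparison of polysomal with monosomal RNA within a genotype asks which transcripts carry many ribosomes. In the control, PMEAMT was depleted from polysomes relative to monosomes, at 3.87 ± 2.85 CPM against 73.9 ± 22.0 CPM (SD, n = 3; -4.25, SE 0.60, adjusted p = 0.0121). In the mutant it stood at 87.1 ± 31.7 CPM in polysomes and 99.1 ± 40.4 CPM in monosomes. The difference between genotypes had a log2 size of 4.06 (SE 0.77) and an adjusted p of 1. Other genes lower in control polysomes code for short proteins: the metallothionein MT3 (-2.30, SE 0.38), the ubiquitin-like proteins SUMO2 (-2.15, SE 0.40) and UBL5 (-1.82, SE 0.28), TOM6 of the mitochondrial import complex (-2, SE 0.31), LEA14 (-2, SE 0.39), PRA1.B2 (-1.91, SE 0.38) and DOT1 (-3.11, SE 0.53). The gene emb1703 was higher in polysomes (1.47, SE 0.26). In the mutant, UBL5 (-2.50, SE 0.29, adjusted p = 0.00195), MT3 (-2.22, SE 0.38), LEA14 (-2.14, SE 0.39), DOT1 (-2.18, SE 0.50), PABN1 (-2.17, SE 0.45) and the arabinogalactan peptide genes AGP21 (-3.74, SE 0.63), AGP12 (-2.51, SE 0.43) and AGP15 (-2.03, SE 0.31) were lower in polysomes. Higher in mutant polysomes were HAC4 (2.82, SE 0.63), UVH3 (2.07, SE 0.45), the myosin gene XIJ (2.03, SE 0.46), SAB (1.99, SE 0.38), PHYLLO (1.87, SE 0.32), the acetyl-CoA carboxylase gene ACC2 (1.86, SE 0.42), emb2410 (1.79, SE 0.39) and CW9 (1.78, SE 0.33). Of these calls, UBL5 in the mutant held whichever library was left out. PMEAMT lost its call only without control polysomal replicate 3 (adjusted p = 0.0524) and AGP15 only without mutant monosomal replicate 2 (0.0623), and each of the others was lost without at least 2 libraries. Without TMM no call was left in the control.

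Coding length ordered this ratio. Across 13107 genes with a mean log2 CPM over 2, the polysome-to-monosome ratio correlated with coding length at a Spearman rho of 0.513 in the control and 0.596 in the mutant. The median log2 ratio was -0.51 and -0.61 in the group of genes with the shortest coding regions (up to 706.5 nt) and 0.35 and 0.41 in the group with the longest (from 1998 nt), of 5 groups of about equal size. Genes are not independent replicates.

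**Figure D4:**
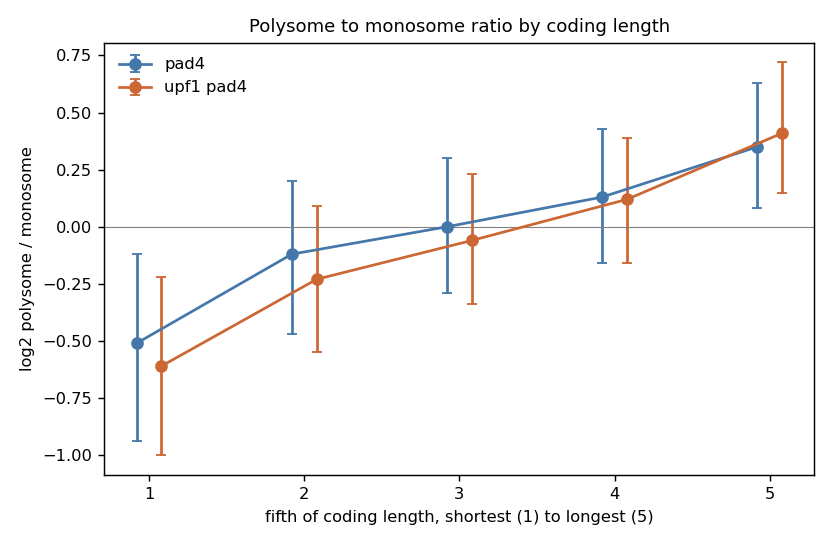
Log2 ratio of polysomal to monosomal RNA (y axis), as the median with quartiles, in 5 groups of genes by coding length (x axis), in the control and the mutant. The median goes from -0.51 to 0.35 in the control and from -0.61 to 0.41 in the mutant.

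NLR receptors, which are long proteins, were higher in polysomes of the control (1 of 34 rose, 5 adjusted over the list alone, median 0.64, adjusted p = 4.18e-05, adjusted p = 0.816 with an estimated correlation), a call lost without control polysomal replicate 1 (0.0577). In the mutant 1 of 34 rose, CHS3 by 1.65 (SE 0.35, 7 adjusted over the list alone, median 0.77, adjusted p = 1.46e-08, adjusted p = 0.739 with an estimated correlation). CHS3 lost its call without mutant monosomal replicate 2 (0.173) or 3 (0.138) or mutant polysomal replicate 2 (0.0718) or 3 (0.137). Photosynthesis genes were lower in polysomes of the control (0 of 38 called, median -0.38, adjusted p = 0.000716, adjusted p = 0.816 with an estimated correlation), though not without control polysomal replicate 1 (0.168). They were also lower in mutant polysomes (0 of 38 called, median -0.61, adjusted p = 2.27e-05, adjusted p = 0.739 with an estimated correlation), though not without mutant monosomal replicate 3 (0.454). Ribosomal protein genes were lower in mutant polysomes (0 of 37 called, 2 lower adjusted over the list alone, median -0.36, 0.000139, adjusted p = 0.739 with an estimated correlation), a call lost without mutant polysomal replicate 3 (0.186), and were not called in the control (0.569). Long non-coding and siRNA precursor RNAs were lower in control polysomes (0 of 7 called, median -1.24, 0.0445, adjusted p = 0.816 with an estimated correlation), a call lost without control monosomal replicate 2 (0.357) or control polysomal replicate 1 (0.175). Guard cell markers were lower there too (0 of 6 called, median -0.60, 0.0287, adjusted p = 0.816 with an estimated correlation), a call lost without control monosomal replicate 2 (0.062) or control polysomal replicate 1 (0.116) or 3 (0.0783). No list test in any contrast took coding length into account. The genotype effects also rose with it (rho 0.174 in monosomal, 0.231 in polysomal RNA, 0.12 and 0.179 for the ratio differences). Whether a list departed from genes of like length was not tested.

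The other lists were not called in the control (adjusted p from 0.269 to 0.795) or the mutant (0.0646 to 0.916). Single omissions changed that for some. In the control, flower markers were called downward without monosomal replicate 1 (0.00247) and jasmonate genes without polysomal replicate 2 (0.0349). Both were lost with an estimated correlation (adjusted p = 0.46 and 0.64). In the mutant, heat shock genes were called upward without monosomal replicate 1 (0.0148) or polysomal replicate 2 (0.0202) or 3 (0.0385), and lost again with an estimated correlation (adjusted p = 0.577 to 0.679). Flowering time regulators were called downward there without monosomal replicate 3 (0.00872) or polysomal replicate 2 (0.0202), and siRNA precursors without monosomal replicate 3 (0.00346). The adjusted p of these calls was 0.541 to 0.597 with an estimated correlation. With replicate block (genotype by number), guard cell markers were not called in the control (0.0801) and flower markers were (down, 0.0162, adjusted p = 0.522 with an estimated correlation). In the mutant that replicate block gave calls for flowering time regulators (down, 0.0443), heat shock genes (up, 0.0196) and siRNA precursors (down, 0.0443). With an estimated correlation the adjusted p was 0.57 to 0.703. Pseudogenes were higher in polysomes of the control (3 of 611 rose, 4.57e-09, adjusted p = 0.354 with an estimated correlation) and the mutant (19 rose, 2.67e-15, adjusted p = 0.165 with an estimated correlation). No class with an NMD feature was called in either genotype (adjusted p from 0.728 to 0.899).

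In the control edgeR called 69 of 20895 genes, 32 higher and 37 lower in polysomes, and in the mutant 231, 119 higher and 112 lower. Libraries did not overlap for 20.9% and 20.5% of tested genes (chance gives 10%). With replicate block (genotype by number) the counts were 481 in the control (181 higher, 300 lower) and 624 in the mutant (282 higher, 342 lower). Without TMM the counts were 0 and 8, and the median ratio of all genes moved from -0.001 to -0.144 in the control and from 0.03 to -0.268 in the mutant. Of the control calls 13 of 89 tested mitochondrial and 5 of 79 chloroplast genes were higher in polysomes, and of the mutant calls 20 and 9. The control count went to 123, 4 and 12 without control monosomal replicate 1, 2 or 3, to 2, 3 and 4 without control polysomal replicate 1, 2 or 3, to 40 without mutant monosomal replicate 2 and to 140 without mutant polysomal replicate 3. The mutant count went to 386, 5 and 44 without mutant monosomal replicate 1, 2 or 3, and to 65 and 44 without mutant polysomal replicate 2 or 3.

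Whether the ratio of polysomal to monosomal RNA differed between genotypes was tested as an interaction. No gene was called by edgeR (0 of 20895; 493 at an unadjusted p under 0.05), while DESeq2 called 2, limma-voom 0 and edgeR without a low-count filter 48. Ribosomal protein genes as a group had a lower ratio in the mutant (median -0.24, camera adjusted p = 0.000302, adjusted p = 0.857 with an estimated correlation), a call lost without mutant monosomal replicate 2 (0.128) or mutant polysomal replicate 3 (0.495). Pseudogenes had a higher ratio (0.0137, adjusted p = 0.634 with an estimated correlation), and the other lists were not called (adjusted p from 0.255 to 0.97). Photosynthesis genes were called downward without control polysomal replicate 1 (0.000919), mutant monosomal replicate 1 (1.28e-10) or mutant polysomal replicate 3 (0.00171), with adjusted p = 0.7, 0.777 and 0.945 with an estimated correlation. Translation factors were called downward without control monosomal replicate 1 (0.0423) or mutant polysomal replicate 1 (0.0169) or 2 (0.0433), which gave 0.767 to 0.842 with an estimated correlation. Vascular markers were called upward without mutant polysomal replicate 2 (0.0433, adjusted p = 0.842 with an estimated correlation). Flower and seed markers were called upward without control monosomal replicate 1 (0.00416, adjusted p = 0.767 with an estimated correlation) or mutant polysomal replicate 3 (0.00851, adjusted p = 0.875 with an estimated correlation). With replicate block they were called too (0.000349, adjusted p = 0.356 with an estimated correlation).

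The last comparison, of the polysome-to-total ratio between genotypes, asks whether changes in polysomes follow those of total RNA. Deviations of total and polysomal libraries of the same number correlated at -0.175 to 0.017, so the numbers pair no libraries here. Mutant total RNA replicates 1 and 2 had a clock index of -2.72 and -2.87, against 4.59 ± 0.91 (SD, n = 3) in mutant polysomal RNA, so the ratio also holds a difference in clock phase. No gene was called by edgeR (0 of 21905; 1508 at an unadjusted p under 0.05), while DESeq2 called 57 and limma-voom 2. Without TMM the median of all genes moved from -0.023 to 0.658. PMEAMT came closest, with a log2 difference of 5.39 (SE 0.85, adjusted p = 0.0609): it stood at 72.2 ± 21.3 and 36.6 ± 24.1 CPM in control and mutant total RNA (SD, n = 3). UPF1 had a difference of 0.74 (SE 0.39, adjusted p = 0.757) and PAD4 of -0.69 (SE 1.34, adjusted p = 0.987). Photosynthesis genes lay higher in mutant polysomes than total RNA gave (median 0.88; adjusted p = 5.96e-10, adjusted p = 0.737 with an estimated correlation). Jasmonate genes (median -1.37, 6 of 24 lower adjusted over the list alone, 8.63e-07, adjusted p = 0.694 with an estimated correlation), splicing regulators (median -0.32, 2 of 20 lower adjusted over the list alone, 0.00952, adjusted p = 0.715 with an estimated correlation) and endoplasmic reticulum stress genes (median -0.63, 1 of 11 lower adjusted over the list alone, 0.000245, adjusted p = 0.694 with an estimated correlation) lay lower. The endoplasmic reticulum stress list had medians of -0.02, 0.77 and -0.13 in mutant total RNA replicates 1, 2 and 3, so replicate 2 lowered its ratio, and without it the adjusted p was 0.0168. Splicing regulators lost their call without control polysomal replicate 2 (0.0595) or 3 (0.0552) or mutant polysomal replicate 1 (0.323). GRP7, a clock-controlled member of the splicing list, had the largest of its differences (-5.19, SE 1.15, adjusted p = 0.277). Salicylic acid genes had a median of -1.36 (adjusted p = 0.579). They were called upward without mutant total RNA replicate 2 (3e-05, adjusted p = 0.391 with an estimated correlation) and downward without replicate 1 (0.0151) or 3 (0.0337), the latter with adjusted p = 0.936 and 0.926 with an estimated correlation. The other lists were not called (adjusted p from 0.0631 to 0.865), and neither were the classes with NMD features (0.62 to 0.701). NLR receptors (0.0631) were called upward without mutant total RNA replicate 2 (5.99e-05), control polysomal replicate 1 (0.00103) or mutant polysomal replicate 1 (0.0302) or 2 (0.0111), which gave 0.56 to 0.978 with an estimated correlation. Clock genes were called downward without mutant total RNA replicate 3 (0.0212, adjusted p = 0.543 with an estimated correlation), and ribosomal protein genes upward without mutant polysomal replicate 3 (0.0189, adjusted p = 0.746 with an estimated correlation). COBL9, the 1 root hair marker tested, had a difference of 3.22 (SE 2.94, adjusted p = 0.914). Without mutant total RNA replicate 3 the test called 97 genes, without mutant monosomal replicate 1 or 3 it called 2 each, and without control total RNA replicate 3 or control polysomal replicate 2 or 3 it called 1 each.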

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

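The tests of mislabelled libraries, of a clock change in all mutant libraries, of harvest time by abundance and of scaling in unscaled counts were chosen only after the result was seen, while those of harvest time over all genes, scaling after TMM and coding length were set before.

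Clock genes differed between genotypes in monosomal and polysomal RNA, where the clock index (morning minus later genes, log2) rose by 6.82 and 7.47, and in mutant total RNA replicate 3, which rose by 7.95. Mutant total RNA replicates 1 and 2 rose by 1.26 and 1.1, which argues against a genotype effect of that size on clock genes in every mutant library. A control library under the label of replicate 3 is argued against by a splicing regulator median of 1.09 in that library, near the 1.23 and 1.3 of replicates 1 and 2. The splicing list does not test the pad4 genotype. A different harvest time cannot be told apart from genotype in the fractions, where all mutant libraries differ from all control ones. Outside the clock list, replicate 3 minus replicates 1 and 2 correlated with the monosomal genotype effect at 0.064 over all genes. Among 453 genes with a mean log2 CPM over 7 it was 0.424. Replicates 1 and 2 (at most 0.004 and -0.12) are no independent reference, since the differences cancel in sum. The 0.064 lies under the bound of 0.1 set beforehand as evidence against harvest time. Yet that bound took the monosomal effect to be mostly harvest time. The effect correlated at 0.531 and 0.439 with replicates 1 and 2 minus the control, which differ little in clock phase, so harvest time may contribute. The slope corrected for noise in the monosomal effect rose from 0.001 up to log2 CPM 2 to 0.344 over 7 (uncorrected -0.001 and 0.392). Deviations of the fractions correlated, so noise was not excluded, and the cause was not tested.

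Salicylic acid and defence genes stood at a median of 4.33 in mutant total RNA replicate 2, against 0.10 and 0.35 in replicates 1 and 3. A control library under this label is argued against by the splicing regulator median of 1.3 in that library (lowest of the other mutant libraries 1.09). That list bears on the upf1 genotype only, so it cannot decide whether the library carried pad4-1. PAD4 had 3131 estimated counts there, against 192 and 257 in mutant replicates 1 and 3, and the pad4 genotype was not tested. A median over all genes of -0.012 from the other mutant libraries decides nothing on scaling of the library, since TMM centres it, but in unscaled counts the defence list lay 3.62 above the median of all genes (at most 0.39 in a control library), a gap that a scaling factor cannot make. No biological explanation was tested, since the labels give no infection or stress for single libraries.

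The polysome-to-monosome ratio rose with coding length. A length bias that varies between libraries is argued against because the slope on length was higher in the polysomal library in 6 of 6 number-matched pairs (mean difference 0.37, SD 0.09, exact sign-flip p = 0.0312, the smallest 6 pairs can give). Fewer ribosomes on short coding regions may account for it: the partial rank correlation with coding length given UTR length was at least 0.511 in each genotype, against at most 0.053 for UTR length given coding length. This is a hypothesis, and a bias shared by all polysomal libraries was not tested.

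Differences between genotypes in a ratio drew attention to 5 lists. Cytosolic ribosomal protein genes (37) had a lower polysome-to-monosome ratio in the mutant (median -0.24, adjusted p = 0.000302, adjusted p = 0.857 with an estimated correlation). In the polysome-to-total ratio, splicing regulators (20) were lower in the mutant (median -0.32, adjusted p = 0.00952, adjusted p = 0.715 with an estimated correlation). Jasmonate genes (24) were lower there too (median -1.37, adjusted p = 8.63e-07, adjusted p = 0.694 with an estimated correlation). Endoplasmic reticulum stress genes (11) were also lower (median -0.63, adjusted p = 0.000245, adjusted p = 0.694 with an estimated correlation), with medians of -0.02, 0.77 and -0.13 in mutant total RNA replicates 1, 2 and 3. Photosynthesis genes (38) were higher (median 0.88, adjusted p = 5.96e-10, adjusted p = 0.737 with an estimated correlation).

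Other splits of the libraries were too few for a share under 0.05 in 5 tests: 1 of 10 splits, the real one, gave as many genes in each. The real and the highest other count were 5638 and 0 in total RNA, 2647 and 1 in monosomal RNA, 2796 and 2 in polysomal RNA, 69 and 0 for polysome against monosome in the control, and 231 and 7 in the mutant. Among the 4 splits that part all 3 number-matched pairs, the highest other count was 0 in both genotypes. For the ratio differences the real count was 0, which every split matches (30 of 30), so this says nothing about chance. The highest other counts were 80 for the polysome-to-monosome and 449 for the polysome-to-total ratio, in splits that keep the genotypes whole in 1 kind of RNA and mix them in the other, so the genotype difference itself enters the ratio.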

How the results depend on the processing

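The tests without mutant total RNA replicates 2 and 3, without control monosomal and polysomal replicate 1, of lists with genotype by number as a block, and of shared calls with single libraries left out were chosen only after the results were seen. Without mutant total RNA replicates 2 and 3 that group has 1 library and the spread comes from the other groups, so values given for this case show only what replicate 1 held. For 229 named gene results, 4363 of 4998 alternative values kept the direction and side of the threshold, 623 lost and 4 gained a call and 8 turned direction. For 168 list and class results, 2582 of 2760 did, 98 lost and 76 gained a call and 4 turned direction. Unless construction explains a change (a stricter threshold, fewer libraries), the cause was not tested.

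At an adjusted p under 0.01, 1943 genes were called in total, 994 in monosomal and 1216 in polysomal RNA, 0 for polysome against monosome in the control (edgeR, 2666 at an unadjusted p under 0.05) and 7 in the mutant, and shared calls were 463 (total and monosomal), 583 (total and polysomal) and 703 (monosomal and polysomal). DESeq2 called 7171, 3874 and 3791 genes in total, monosomal and polysomal RNA and limma-voom 5544, 2793 and 2306. For polysome against monosome in the control, the count was 0 without TMM (1708 unadjusted), 577 without a low-count filter, 493 with DESeq2, 33 without organelle genes, 200 with replicate block (number as a covariate), 481 with replicate block (genotype by number), 104 from the libraries of the contrast alone and 5 without control monosomal and polysomal replicate 1. In the mutant it was 8 without TMM, 797 without a filter, 763 with DESeq2, 360 with limma-voom, 624 with replicate block (genotype by number), 7 from the libraries of the contrast alone and 369 without control monosomal and polysomal replicate 1. For the difference of that ratio it was 48 without a filter and 2 with DESeq2. For the polysome-to-total difference it was 3 without TMM, 72 without a filter, 57 with DESeq2, 2 with limma-voom and, from 1 mutant total RNA library, 23 without mutant total RNA replicates 2 and 3.

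Camera with an estimated correlation called 0 lists in total RNA, 0 in monosomal RNA, 1 in polysomal RNA, 0 in either polysome-to-monosome contrast and 0 in either ratio difference, where the preset correlation had called 10, 11, 7, 4, 3, 1 and 4. With fry the counts were 6 in total, 10 in monosomal and 9 in polysomal RNA and 0 in the 4 ratio contrasts. The replicate block (genotype by number) gave 6 lists for the mutant polysome-to-monosome ratio and 2 for its difference, which was 4 without control monosomal and polysomal replicate 1. Without mutant total RNA replicates 2 and 3 the polysome-to-total difference had 7 lists, which with 1 library in that group is no usable comparison. Without control monosomal and polysomal replicate 1, lists called were flower markers (0.0146), jasmonate genes (0.00694) and photosynthesis genes (0.00136) in polysomal RNA and flower markers in the control polysome-to-monosome ratio (0.029), with adjusted p = 0.326, 0.168, 0.602 and 0.668 with an estimated correlation. In the difference of that ratio they were photosynthesis genes (0.00129), translation factors (0.00972) and flower markers (0.00598), with adjusted p = 0.736, 0.715 and 0.715 with an estimated correlation. Calls lost there were senescence genes in monosomal RNA (0.0525) and photosynthesis genes (0.205) and guard cell markers (0.0615) in the control ratio. Without organelle genes, photosynthesis genes in polysomal RNA (0.0373) and NLR receptors in the polysome-to-total ratio (0.0396) were called, with adjusted p = 0.727 and 0.884 with an estimated correlation. NMD feature classes called in monosomal RNA (1 with the preset correlation) were 0 with an estimated correlation, 0 with fry and 2 without control monosomal and polysomal replicate 1, and in polysomal RNA (2) they were 0 with an estimated correlation and 1 with fry. In total RNA all 3 classes were called with each of these tests.

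With single libraries left out, counts ran from 2047 to 6109 in total, 1378 to 2887 in monosomal and 1418 to 3152 in polysomal RNA, 2 to 140 and 5 to 386 for polysome against monosome in control and mutant, 0 to 0 for the difference of that ratio and 0 to 97 for the polysome-to-total difference. Lists called ran from 8 to 13, 9 to 14, 7 to 9, 0 to 5, 3 to 5, 0 to 3 and 3 to 6 in the same order, and NMD classes from 2 to 3, 1 to 2 and 0 to 2 in total, monosomal and polysomal RNA. Shared calls ran from 889 to 1695 (total and monosomal), 964 to 2015 (total and polysomal) and 1058 to 1675 (monosomal and polysomal).

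Directions turned for SAG13 in total RNA (-0.218 without mutant total RNA replicates 2 and 3, from 1 mutant library, adjusted p = 0.855), for UPF1 in monosomal RNA (0.412 without TMM) and in polysomal RNA (0.089 without TMM, -0.713 to 0.012 with single libraries left out), and for PAD4 in the polysome-to-total ratio (0.074 without TMM, 0.824 with limma-voom, 1.454 without mutant total RNA replicates 2 and 3, from 1 library, -1.25 to 1.298 with single libraries left out). The adjusted p of photosynthesis genes in monosomal RNA ran from 0.000365 to 0.557 with single libraries left out, upward without mutant monosomal replicate 1 (0.0182, adjusted p = 0.652 with an estimated correlation). In the polysome-to-total ratio that of salicylic acid genes ran from 3e-05 to 0.716, upward without mutant total RNA replicate 2 (3e-05, adjusted p = 0.391 with an estimated correlation) and, from 1 library, without replicates 2 and 3 (4.16e-05, adjusted p = 0.422 with an estimated correlation). That of ribosomal protein genes ran from 0.0189 to 0.99, upward without mutant polysomal replicate 3 (0.0189, adjusted p = 0.746 with an estimated correlation).

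With 3 libraries per group, changes of 2-fold were recovered in at most 4.1% of simulated cases in any comparison. For the ratio contrasts, where few or no genes were called, most changes of that size would thus be missed. The simulations changed far fewer genes than were called between genotypes, which makes the adjusted threshold stricter. Their shares therefore do not give the recovery in the genotype comparisons.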

Other observations

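The tests of the 4 gene lists below were chosen only after the results were seen, and their p values were adjusted over 28 tests (4 lists in 7 comparisons).

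Genes of cell division were lower in the mutant. Of 20 mitotic genes 17 fell in total RNA (median -1.66, adjusted p = 4.83e-09, adjusted p = 0.5 with an estimated correlation), 9 in monosomal RNA (2.37e-10, adjusted p = 0.31 with an estimated correlation) and 7 in polysomal RNA (2.37e-10, adjusted p = 0.31 with an estimated correlation), and none rose. The cyclin gene CYCA1;1 (-2.45, SE 0.29) and PLE, a microtubule-associated protein gene of cytokinesis (-2.06, SE 0.33), are examples in total RNA. Of 10 DNA replication genes 9 fell in total RNA (median -1.27, 7.48e-06, adjusted p = 0.31 with an estimated correlation), 2 in monosomal RNA (0.000606, adjusted p = 0.525 with an estimated correlation) and 5 in polysomal RNA (1.74e-06, adjusted p = 0.31 with an estimated correlation). They include PCNA1, the sliding clamp of DNA polymerase (-1.58, SE 0.23), and MCM3 of the replicative helicase (-1.5, SE 0.23). In control polysomes against monosomes DNA replication genes stood higher (median 0.58, 0 of 10 called, 0.00333, adjusted p = 0.632 with an estimated correlation).

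Of 9 iron deficiency genes 4 rose in total RNA (median 2.77, adjusted p = 0.0138, adjusted p = 0.73 with an estimated correlation), and 6 each in monosomal and polysomal RNA (both 2.21e-06, adjusted p = 0.0809 with an estimated correlation). The iron-regulated transcription factor gene bHLH38 rose by 5.08 (SE 0.81) in total RNA and the ferric reductase gene FRO3 by 2.77 (SE 0.42). Of the phosphate starvation genes 3 of 6 rose in total RNA, among them SPX1, a phosphate-sensing regulator (2.13, SE 0.56), and SRG3 (3.36, SE 0.54), while the list was not called (0.0508). In monosomal RNA 2 of 7 rose (0.0142, adjusted p = 0.658 with an estimated correlation) and in polysomal RNA 2 of 7 (0.0469, adjusted p = 0.73 with an estimated correlation). The other 15 tests of these lists were not called.

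A hypothesis is that mutant leaves held fewer dividing cells. It needs both the mitotic and the DNA replication list to be lower in total RNA, and the larger of the 2 adjusted p was 7.48e-06, but neither list is called with an estimated correlation (adjusted p = 0.5 and 0.31). Lower expression per cell would give the same values, and the mitotic list was drawn up after division genes had been seen among the lowest.

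The floral gene PI stood at 1.54, 19.6 and 19.3 CPM and the tapetum gene LTP12 at 0.4, 51.3 and 39.6 CPM in control monosomal replicates 1, 2 and 3, while PI in control total RNA stood at 3.28, 1.09 and 0.617 CPM.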
